A study of Mus musculus with 6 samples.

How the data were processed

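Hindlimb muscle macrophages of C57BL/6 mice were profiled by droplet single-cell RNA sequencing (10x Genomics, 3′ tags). Per the labels' protocols, muscle was digested with collagenase, dispase and DNase, cells were enriched on Percoll, and live CD45+CD64+MerTK+ cells were sorted before capture. The labels name 3 groups of 2 libraries, and each library held cells pooled from 3 mice. Uninfected injured mice received cardiotoxin, a snake venom toxin that kills muscle fibres, and were sampled 4 days later. Infected uninjured muscle came from mice given 5 cysts of the ME49 strain of the parasite Toxoplasma gondii by mouth and sampled on day 28 of infection. Infected injured muscle received cardiotoxin on day 24 of the same infection and was also sampled on day 28. Muscle that was neither infected nor injured was not analysed here. The study's design text speaks of opposite legs for injured and uninjured infected muscle. The labels do not say whether these libraries of an experiment came from the same mice. The mice were 8 to 12 weeks old.

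Reads were processed with Cell Ranger 2.02 on the mm10 genome, per the submitters' processing notes. The authors deposited whole-number UMI counts per gene and cell barcode for 27998 genes in each library, and these counts were used without any earlier normalisation. A UMI (unique molecular identifier) marks 1 captured transcript, so repeated PCR copies were counted once. Counting favours the 3′ end of transcripts, and members of near-identical families (such as Gbp, Serpina3, Tgtp and H2-Q genes) share sequence, so their individual values are uncertain. Among the gene entries, 121 shared a symbol with another entry and were kept apart by their Ensembl identifier. Gene positions are those of the GENCODE annotation on mm10, in which all 383 genes looked up were found.

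Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed 7 of 12120. The doublet caller in scanpy 1.11.5 marked only 0.272% of barcodes and was treated as not having worked. In its place, the barcodes with the highest doublet scores were removed at the rate expected from loading, 0.8% per 1000 barcodes, which took 386, 1 of them among the 7 already removed, and left 11728 cells. Cells were clustered on 2000 variable genes, 30 principal components and 15 neighbours (Leiden resolution 1, leidenalg 0.10.2), giving 16 clusters. A cluster was set aside when at least 3 of its 10 leading genes were markers of a cell type other than macrophages or monocytes, from lists of 13 cell types. This set aside 2 clusters, of 132 neutrophil-like and 129 T or NK cell-like cells. The other 11467 cells, called retained cells here, were not given a cell type name of their own, because some of their clusters held more markers of another type than of macrophages among their leading genes.

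Raw counts of the retained cells were summed per library, since cells are not replicates. The sums ranged from 4448159 to 59793654 UMIs. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, TMM scaling, a filter on expression at a minimum count of 10, and a Benjamini-Hochberg threshold of 0.05. One model held all 6 libraries, which left 3 residual degrees of freedom, and 11279 genes were tested. Fold changes are on the log2 scale with the default prior count of edgeR. Errors are standard errors (SE), obtained as the absolute log2 fold change divided by the square root of its quasi-likelihood F. A prior count of 2 was used only for the log2 levels behind the comparisons of replicate libraries. Levels are counts-per-million values (CPM), relative to all UMIs of the retained cells in a library. A group with 0 counts was given a floor of 3 counts over the group to bound its fold change. The libraries of a group are pools from separate experiments per the labels, so the p-values measure the spread between such pools within groups.

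Before the data were examined, 16 lists of macrophage programmes and the 13 cell type lists were fixed, together with the tests, the alternatives and the rule for naming genes. The rule took, for the comparisons with infected injured muscle, the 10 genes with the highest and the 10 with the lowest fold change among those with an adjusted p under 0.05, a mean CPM of at least 20 and no overlap between the libraries of the groups. For the remaining comparison it took 5 and 5. It also took up to 4 members of each programme list by p, further members where a list count is described, the sort markers, and the 3 most abundant markers of each other cell type. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma 3.58.1). Adjusted p-values of programme lists are over the 16 lists within a comparison.

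Variation between cells was measured in each library as 1 minus the Pearson correlation between log-normalised profiles, taken as the median over pairs of cells. Each cell was thinned to 3449 UMIs and 468 cells were drawn from each library, 20 times. The shallower cells left out numbered 125 and 159 in uninfected injured, 50 and 121 in infected uninjured, and 6 and 21 in infected injured libraries. Groups of 2 libraries allow a smallest exact two-sided permutation p of 0.333, so no such comparison could pass 0.05. Shares of cells have exact 95% binomial intervals, which cover counting error only. For a share of 0 the limit given is 3 cells of the total.

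The edgeR and camera steps were tested on simulated counts for 11279 genes with 200 changed genes. For infected injured against uninfected injured, 64% of 2-fold and 93% of 4-fold changes were recovered, and 9.25% of calls were false. The values were 52%, 89% and 12.4% for infected injured against infected uninjured, and 60%, 91% and 7.36% for infected uninjured against uninfected injured. The share of false calls was thus above the nominal 5% in each simulation. Camera gave p of at most 1.10e-42 for a list raised 2-fold and at least 0.205 for an unchanged list. Genes were drawn independently there, while the estimated correlation within the programme lists reached 0.577 in the data. The simulation therefore could not test camera on correlated lists. In simulated cells of 1 profile, the thinned distance was 0.248 at 4000 and 0.247 at 12000 UMIs per cell, against 0.202 and 0.0803 without thinning.

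Replicate libraries differed by more than sampling noise, with chi-square values per degree of freedom of 37.9, 16.0 and 21.9, so none was a copy of another. The labels give the replicate number as the number of the experiment, which pairs the libraries across groups. Across genes, the differences between experiments correlated at 0.028 between uninfected injured and infected uninjured, 0.26 between uninfected injured and infected injured, and 0.12 between the infected groups. The fit with the experiment as a block was an alternative. The other alternatives were DESeq2 1.42.0 and limma, other scalings and count filters, other cell filters, equal cells or depth per library, all kept cells, other clusterings and leaving out each library in turn.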

Results

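Single-cell RNA sequencing of sorted hindlimb muscle macrophages was available for 6 libraries, with 2 libraries in each of 3 groups. The groups were uninfected injured muscle, infected uninjured muscle and infected injured muscle, where injury was a cardiotoxin injection 4 days before sampling and infection was day 28 of Toxoplasma gondii infection. Total UMI counts were 66361653 and 12701948 in the uninfected injured libraries 1 and 2, 4629988 and 16337986 in the infected uninjured libraries, and 13653980 and 6450427 in the infected injured libraries. Barcodes numbered 6338 and 1622, 546 and 1977, and 976 and 661 in the same order. Median UMIs per barcode were 9230 and 6694.5, 8346.5 and 8090, and 13011.5 and 9034. The genes behind the sort were measured in the retained cells of every library. Fcgr1, which encodes CD64, ranged from 218 to 352 CPM, Mertk from 30.5 to 61.1 CPM and Ptprc, which encodes CD45, from 230 to 374 CPM.

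The first comparison, infected injured against uninfected injured muscle, asked how chronic infection altered the retained cells of injured muscle. Most genes of the interferon-gamma response, MHC class I presentation and glycolysis lists were called higher in the infected injured libraries, as were 8 of 15 MHC class II genes. These lists passed with camera at its preset correlation and none of them passed with an estimated correlation (adjusted p 0.0930 to 0.306). Nos2, the inducible nitric oxide synthase, had 0 UMIs in both uninfected injured libraries and 11.6 and 20.7 CPM in the infected injured libraries, at least 351-fold higher (adjusted p = 2.58e-05). Saa3, an acute-phase serum amyloid, rose from 2.27 and 3.48 CPM to 331 and 763 CPM, a log2 fold change of 7.82 ± 0.48 (SE, n = 2 libraries per group, adjusted p = 6.74e-05 in edgeR). Retnla, a secreted protein typical of alternatively activated macrophages, fell from 89.2 and 156 CPM to 0 and 0.474 CPM. With 3 UMIs in infected injured against 7265 in uninfected injured libraries, the ratio of its levels was 0.00155 (95% counting interval 3.19e-04 to 0.00452, adjusted p = 2.89e-04).

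Among the other genes with the largest rises were Upp1, a uridine phosphorylase, at a log2 fold change of 7.05 ± 0.27 (adjusted p = 7.31e-08), and Gm15056 at 7.25 ± 0.73 (adjusted p = 0.00811). Iigp1, an immunity-related GTPase that acts on the vacuole of Toxoplasma, rose by 6.64 ± 0.41 (adjusted p = 2.39e-04), and Serpina3g, a protease inhibitor, by 5.59 ± 0.46 (adjusted p = 0.00222). Cxcl9, a chemokine that attracts T cells, rose by 7.13 ± 0.75 (adjusted p = 0.00983). That call ended without infected injured library 1 (adjusted p = 0.0620), without infected injured library 2 (0.0681) and with the experiment as a block (0.0595). The calls of Gbp2b, Serpina3f and Ly6i, also higher, and of Fcrls and Itga6, lower, ended without at least 1 library, with an adjusted p of up to 0.177 for Serpina3f without uninfected injured library 1. Fcrls also lost its call with the experiment as a block (adjusted p = 0.0536).

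The genes with the largest falls after Retnla included Gpr34, a receptor for lysophosphatidylserine, at −2.73 ± 0.19 (adjusted p = 2.60e-06). Gas6, a ligand of MerTK, fell by 2.58 on the log2 scale (SE 0.24, adjusted p = 9.79e-05). Ccr2, the chemokine receptor of recruited monocytes, went from 466 and 477 CPM to 160 and 121 CPM, a change of −1.55 ± 0.17 (adjusted p = 1.30e-04). Sesn1, a stress-inducible gene, changed by −1.61 ± 0.16 and Sulf2, a sulfatase of the cell surface, by −1.46 ± 0.18, with adjusted p of 5.21e-05 and 3.03e-04. Fibronectin (Fn1) changed by −2.43 ± 0.32 (adjusted p = 0.00557, and 0.0795 with equal cells per library), and transferrin (Trf) by −2.15 ± 0.31 (adjusted p = 0.00898, and 0.0525 with the experiment as a block).

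On mm10, Nos2 (ENSMUSG00000020826) lies on chromosome 11 at 78920787 to 78960254, Saa3 (ENSMUSG00000040026) on chromosome 7 at 46711998 to 46715700, Upp1 (ENSMUSG00000020407) on chromosome 11 at 9118103 to 9136170 and Iigp1 (ENSMUSG00000054072) on chromosome 18 at 60376027 to 60392634. Retnla (ENSMUSG00000061100) lies on chromosome 16 at 48842551 to 48844461, Gas6 (ENSMUSG00000031451) on chromosome 8 at 13465374 to 13494490 and Ccr2 (ENSMUSG00000049103) on chromosome 9 at 124101950 to 124113557. All of these are annotated as protein-coding genes.

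**Figure D1:**
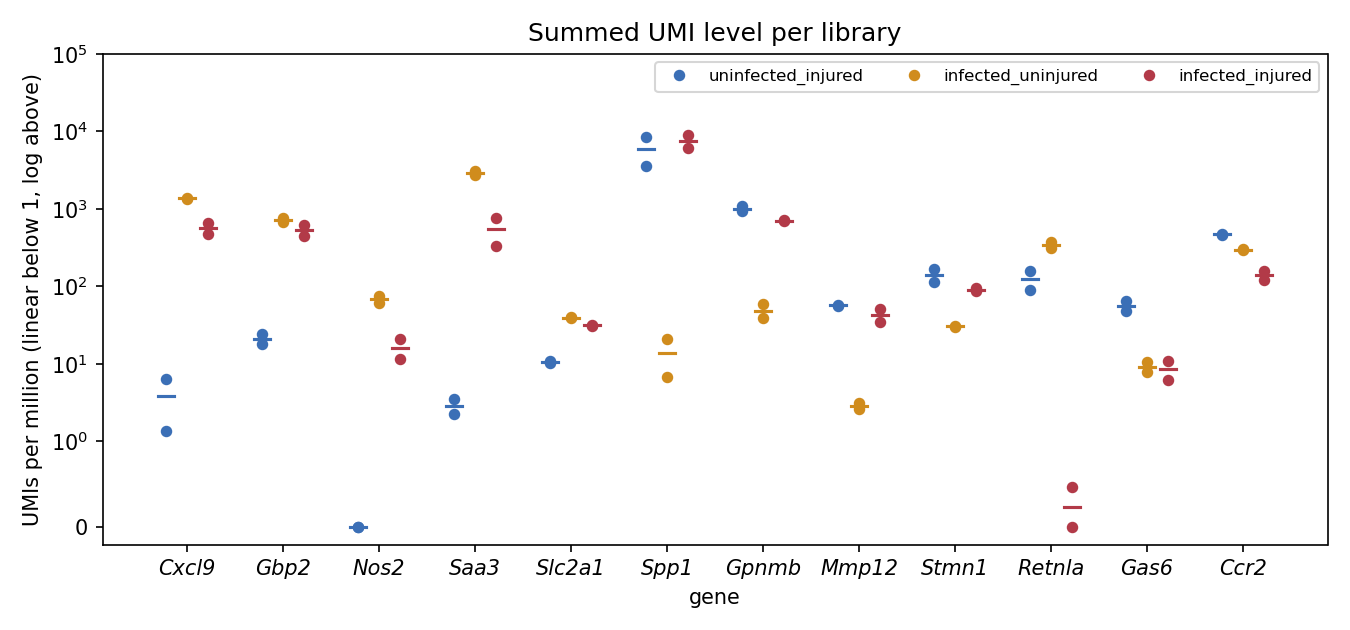
Summed UMI level per library (CPM, linear below 1 and logarithmic above) of 12 genes in the 3 groups, where each dot is a library and each bar the mean of 2 libraries. Retnla lay between 89.2 and 377 CPM in the libraries of the other groups and at 0 and 0.474 CPM in infected injured libraries, and Gpnmb lay at 58.7 and 38.8 CPM in infected uninjured libraries and between 694 and 1089 CPM in the rest.

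The interferon-gamma response list carried the largest change in infected injured against uninfected injured muscle. Of its 32 measured members, 27 rose (31 adjusted over the list alone), and the median log2 fold change was 2.67, also with Nos2 at its bound. Gbp2, a guanylate-binding protein active against intracellular parasites, rose by 4.82 ± 0.24, the transcription factor Batf2 by 3.39 ± 0.18 and Cd274, which encodes PD-L1, by 2.63 ± 0.17. The list stood apart from other genes in camera (adjusted p = 7.67e-109), with adjusted p = 0.0930 with an estimated correlation. MHC class I genes rose in 19 of 21 cases (20 adjusted over the list alone), with a median of 1.49 and an adjusted p of 8.86e-34, against adjusted p = 0.0930 with an estimated correlation. They included the peptide transporter Tap1 at 2.00 ± 0.17 and the immunoproteasome subunit Psmb9 at 1.70 ± 0.16. MHC class II genes rose in 8 of 15 cases (10 adjusted over the list alone), among them H2-DMb1 at 1.22 ± 0.21. Their median was 1.04 (camera adjusted p = 4.71e-08, and adjusted p = 0.306 with an estimated correlation). By contrast, the type I interferon list had a median of 0.08 (adjusted p = 0.600), with 2 of 25 members higher, Zbp1 at 1.56 ± 0.15 and Isg15 (2 higher and 2 lower adjusted over the list alone). The call of Isg15 ended without uninfected injured library 2 (0.0656) or infected injured library 2 (0.0666). Cells resembling T or NK cells, kept out of these sums, were 2.17% and 1.22% of the sorted cells in infected injured libraries and 0.382% and 0% in uninfected injured libraries.

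Glycolysis and hypoxia genes formed the next large group, with 18 of 24 members higher (20 adjusted over the list alone) and a median of 0.94. The glucose transporter Slc2a1 rose by 1.76 ± 0.15, the lactate transporter Slc16a3 by 1.46 ± 0.17 and pyruvate kinase (Pkm) by 1.28 ± 0.18. The camera adjusted p was 1.88e-19, with adjusted p = 0.0930 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.30, with cytochrome c (Cycs) the member that rose (1 also adjusted over the list alone), a camera adjusted p of 1.09e-04 and adjusted p = 0.565 with an estimated correlation. Of 20 inflammatory monocyte genes, 8 rose and 2 fell (10 and 3 adjusted over the list alone), with a median of 0.49. Ly6a rose by 4.91 ± 0.34 and Ly6c2 by 1.41 ± 0.17, while Ccr2 and Cd177 fell. This list had a camera adjusted p of 4.47e-06 and adjusted p = 0.0930 with an estimated correlation. In the list of inflammatory cytokines and chemokines, 4 of 24 rose and 1 fell (7 and 1 adjusted over the list alone), with Il27 at 3.62 ± 0.29 and Tnf at 1.47 ± 0.15. Its median was 0.50, its camera adjusted p 2.28e-04, and it had adjusted p = 0.316 with an estimated correlation.

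Alternative activation genes moved the other way, with 5 of 19 lower and 2 higher (7 and 2 adjusted over the list alone) and a median of −0.47. Mgl2, a lectin, changed by −4.50 ± 0.43, while the transglutaminase Tgm2 rose by 1.52 ± 0.19. The camera adjusted p was 2.67e-04, with adjusted p = 0.365 with an estimated correlation. Mgl2 was also a leading gene of a dendritic cell-like cluster at Leiden resolution 2.0, with 248 and 35 uninfected injured and 2 and 0 infected injured cells. No dendritic cell-like cluster was set aside at resolution 1, so the retained cells can include such cells. Resident macrophage genes split, with 5 of 23 lower and 4 higher (8 and 4 adjusted over the list alone) and a median of −0.81. Gas6 and the leukotriene C4 synthase Ltc4s (−1.87 ± 0.28) fell, while complement C4b rose by 3.99 ± 0.32. The list's adjusted p of 0.0136 was lost without uninfected injured library 2 (0.0940) and without infected injured library 1 (0.231), and was adjusted p = 0.449 with an estimated correlation. The remaining lists did not pass. Their median log2 changes were −0.24 for muscle repair factors (1 of 20 higher, 2 lower; adjusted p = 0.539), −0.17 for lipid handling and lysosome (1 of 26 higher, 4 lower; 0.158), −0.30 for complement and efferocytosis receptors (3 of 19 higher, 2 lower; 0.25), 0.28 for iron and haem handling (2 of 19 higher, 3 lower; 0.624) and −0.07 for dissociation stress (1 of 24 higher, 1 lower; 0.681). Adjusted over the list alone, the higher and lower members of these lists were 4 and 3, 1 and 4, 5 and 5, 8 and 6, and 1 and 1, so iron and haem genes moved both ways. Cell cycle genes had a median of −0.14 (adjusted p = 0.209). edgeR, DESeq2 and limma each called 0 of its 34 members, of which 4, 2 and 4 had an unadjusted p under 0.05.

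In all, edgeR called 1009 of 11279 genes between infected injured and uninfected injured muscle, 599 higher and 410 lower, of which 559 changed over 2-fold. The count was 1597 with the experiment as a block and 561 without infected injured library 1. Without scaling beyond the total count, the median of all genes moved to −0.19 and 34.3% of calls were higher, against 59.4% with TMM scaling.

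The second comparison, infected injured against infected uninjured muscle, asked what injury changed in the retained cells of infected muscle. In the lists of lipid handling and lysosome, repair factors and the cell cycle, 14 of 26, 6 of 20 and 16 of 34 genes were called higher after injury, and 11 of 32 interferon-gamma response genes were called lower. None of these lists passed with an estimated correlation (adjusted p 0.0952 to 0.265). Spp1, which encodes osteopontin, rose from 6.74 and 20.7 CPM to 9039 and 6142 CPM, a log2 fold change of 9.08 ± 0.92 (n = 2 libraries per group, adjusted p = 0.0066, and 0.0511 with the experiment as a block). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose from 58.7 and 38.8 CPM to 717 and 694 CPM, or 3.94 ± 0.24 (adjusted p = 8.98e-06). Retnla again fell, from 377 and 310 CPM to 0 and 0.474 CPM, a ratio of 4.79e-04 (95% counting interval 9.88e-05 to 0.0014, adjusted p = 3.25e-04). Nos2 changed by −2.07 ± 0.25 (adjusted p = 0.0023), from 60.9 and 74.9 CPM to 11.6 and 20.7 CPM.

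Further genes with large rises were Syngr1, a vesicle membrane protein, at 4.94 ± 0.23 (adjusted p = 4.86e-07), the macrophage elastase Mmp12 at 4.06 ± 0.26 (adjusted p = 1.78e-05) and the fatty acid-binding protein Fabp4 at 3.53 ± 0.33 (adjusted p = 7.85e-04). Complement C4b fell from 105 and 143 CPM to 22.8 and 38.0 CPM (adjusted p = 0.00323). Other falls included the formyl peptide receptor Fpr2 at −1.94 ± 0.18, the acyl-CoA synthetase Acsl1 at −1.89 ± 0.16 and Tmcc1 at −1.82 ± 0.14. Their adjusted p-values were 1.33e-04, 6.87e-05 and 5.20e-05. Saa3 changed by −2.38 ± 0.36 (adjusted p = 0.00677), a call that ended without infected uninjured library 1 (0.0599) or library 2 (0.0656). Complement C3 changed by −2.16 ± 0.31 (adjusted p = 0.00772, and 0.0753 without infected uninjured library 2). The rule also took Pdpn, Il7r, Cd9, Gpr183 and Fcrls, which were higher, and Gm15056 and Gbp2b, which were lower. Their calls ended without at least 1 library, with an adjusted p of up to 0.255 for Fcrls without infected uninjured library 2. With the experiment as a block the calls of Fcrls (0.0877) and Gm15056 (0.0854) ended as well. On mm10, Spp1 (ENSMUSG00000029304) lies on chromosome 5 at 104435118 to 104441050, Gpnmb (ENSMUSG00000029816) on chromosome 6 at 49036546 to 49070929, Syngr1 (ENSMUSG00000022415) on chromosome 15 at 80091334 to 80119501 and Mmp12 (ENSMUSG00000049723) on chromosome 9 at 7344381 to 7369499, all protein-coding.

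Lipid handling and lysosome genes were the list with the clearest rise after injury. Of 26 members, 14 rose and 1 fell (16 and 3 adjusted over the list alone), with a median of 1.45. Besides Syngr1, Gpnmb and Fabp4, the tetraspanin Cd63 rose by 2.27 ± 0.24, the fatty acid-binding protein Fabp5 by 2.47 ± 0.27 and galectin-3 (Lgals3) by 1.66 ± 0.21. The camera adjusted p was 5.88e-28, with adjusted p = 0.0952 with an estimated correlation. Of 34 cell cycle genes, 16 rose (19 adjusted over the list alone), with a median of 1.23. They included Stmn1, a regulator of microtubules, at 1.64 ± 0.17, Birc5 (survivin) at 1.84 ± 0.22 and cyclin B2 (Ccnb2) at 1.89 ± 0.26. That list had a camera adjusted p of 8.18e-16 and adjusted p = 0.265 with an estimated correlation. Muscle repair factors rose in 6 of 20 cases and fell in 1 (8 and 1 adjusted over the list alone), with Spp1, Mmp12, Lgals3 and Anxa1 among them. Their median was 0.57, the camera adjusted p 1.98e-06, and adjusted p = 0.0952 with an estimated correlation.

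Interferon-gamma response genes fell in 11 of 32 cases (19 adjusted over the list alone) in infected injured against infected uninjured muscle, with a median of −0.81. Cd274 changed by −1.33 ± 0.16 besides Nos2, and the list had a camera adjusted p of 5.54e-13 and adjusted p = 0.265 with an estimated correlation. T or NK cell-like cells were 2.17% and 1.22% of sorted cells in infected injured and 3.89% and 2.88% in infected uninjured libraries. Resident macrophage genes fell in 7 of 23 cases (8 adjusted over the list alone), with the hyaluronan receptor Lyve1 at −4.26 ± 0.55 (median −0.60, camera adjusted p = 2.83e-05, and adjusted p = 0.265 with an estimated correlation). Alternative activation genes fell in 4 of 19 cases, Retnla among them, and rose in 2 (the same counts adjusted over the list alone), with a median of −0.38, a camera adjusted p of 1.69e-05 and adjusted p = 0.265 with an estimated correlation. Inflammatory monocyte genes fell in 7 of 20 cases and rose in 1 (9 and 2 adjusted over the list alone), among them Ccr2 at −1.02 ± 0.17. The camera adjusted p of that list was 0.0039, lost without infected injured library 2 (0.0760), and adjusted p = 0.265 with an estimated correlation. Genes of dissociation and early stress, which tissue digestion can raise, fell in 8 of 24 cases and rose in 1 (10 and 1 adjusted over the list alone), with Klf6 at −1.05 ± 0.17. Their camera adjusted p was 2.17e-04, with adjusted p = 0.476 with an estimated correlation.

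Glycolysis and hypoxia genes were lower in 7 of 24 cases and higher in 2 (the same counts adjusted over the list alone), with Hif1a at −0.93 ± 0.14 and Hilpda at 1.52 ± 0.22. Their camera adjusted p was 0.0287 (0.350 without infected uninjured library 2), and adjusted p = 0.493 with an estimated correlation. MHC class I genes had a median of −0.23 with 2 of 21 lower (1 adjusted over the list alone) and a camera adjusted p of 0.0199. It was 0.217 without infected uninjured library 2 and 0.0502 without infected injured library 1, and adjusted p = 0.586 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.20 and a camera adjusted p of 0.0199, lost without infected uninjured library 1 (0.191) and infected injured library 1 (0.170), and adjusted p = 0.586 with an estimated correlation. edgeR called 0 of its 37 members, of which 4 had an unadjusted p under 0.05, while DESeq2 called 2 and limma 2. Lists that did not pass had medians of 0.23 for type I interferon (3 of 25 higher; adjusted p = 0.0922), −0.39 for MHC class II (2 of 15 lower; 0.0792), −0.05 for inflammatory cytokines and chemokines (2 of 24 higher, 5 lower; 0.0865), 0.03 for complement and efferocytosis receptors (5 of 19 higher, 3 lower; 0.107) and −0.11 for iron and haem handling (2 of 19 lower; 0.349). Adjusted over the list alone, their higher and lower members were 3 and 0, 1 and 3, 3 and 5, 6 and 4, and 1 and 3.

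**Figure D2:**
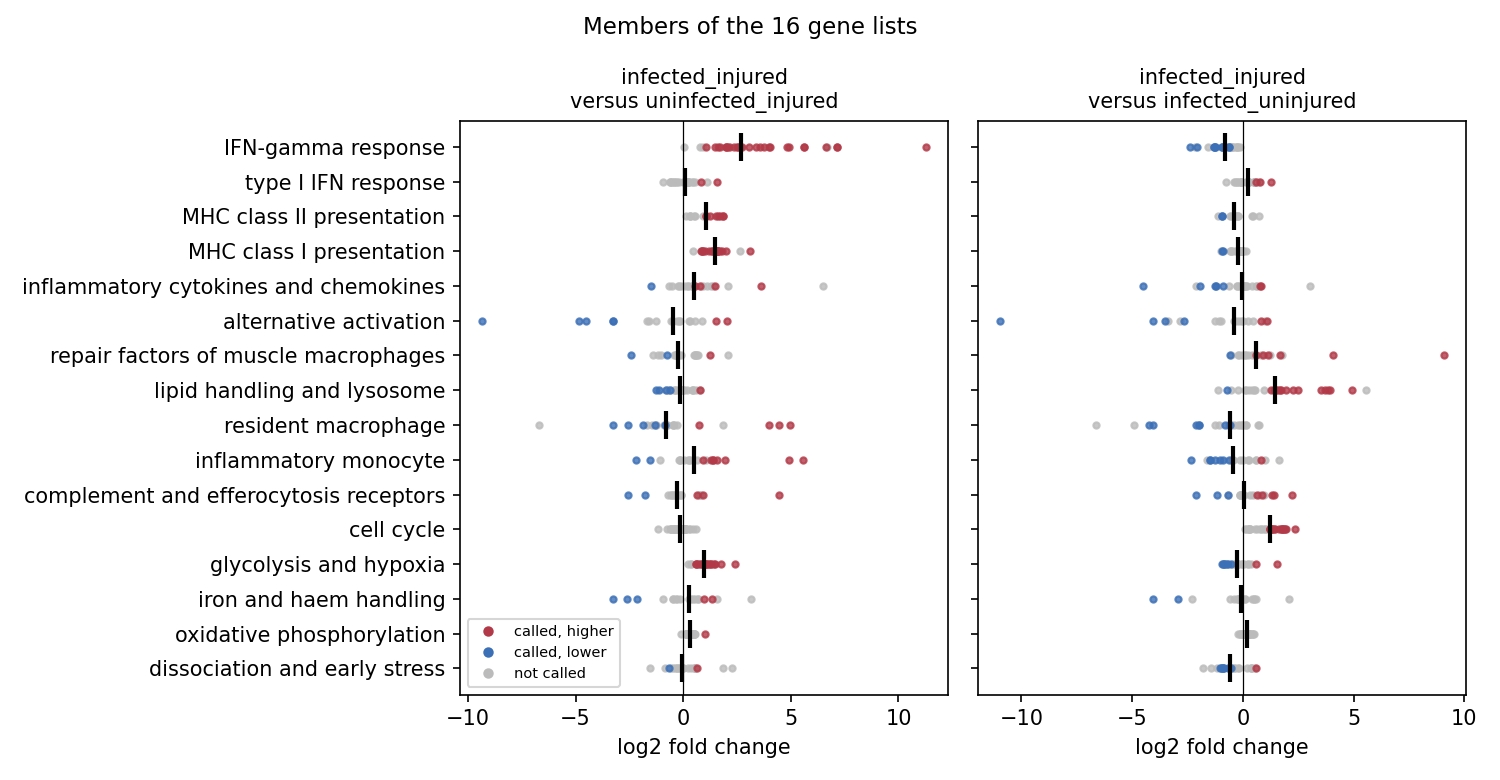
Log2 fold change of every measured member of the 16 gene lists in infected injured against uninfected injured muscle (left) and against infected uninjured muscle (right), where each dot is a gene, its colour shows its call in edgeR, and black ticks are list medians. With the outermost dots (Nos2 on the left, Retnla in both panels) fitted values of genes with few or no UMIs in 1 group, the median of the interferon-gamma response list was 2.67 on the left and −0.81 on the right, and that of lipid handling and lysosome genes −0.17 and 1.45.

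In all, edgeR called 1527 genes between infected injured and infected uninjured muscle, 732 higher and 795 lower, 632 of them over 2-fold. The count was 718 without infected uninjured library 1, 370 without infected uninjured library 2 and 473 without infected injured library 1. Without scaling beyond the total count, 37.5% of calls were higher, against 47.9% with TMM scaling.

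The third comparison, infected uninjured against uninfected injured muscle, differed in both infection and injury, so its changes belong to neither alone. Nos2 was at least 1726-fold higher in infected uninjured muscle, and Saa3 was higher by 10.20 ± 0.53 (adjusted p = 8.62e-06), at 3132 and 2744 CPM. Spp1 changed by −8.56 ± 0.90 (adjusted p = 0.00288), Syngr1 by −5.73 ± 0.23 (adjusted p = 2.54e-08), Fcrls by −5.55 ± 0.55 (adjusted p = 0.00234) and Gpnmb by −4.27 ± 0.24 (adjusted p = 3.77e-07). Gm15056 rose by 9.89 ± 0.74 and Gbp2b by 9.51 ± 0.69, with adjusted p of 0.00119 and 9.36e-04. The rule also took Ubd, which was higher, and Atp6v0d2, which was lower, whose calls ended without single libraries (adjusted p up to 0.207 for Ubd without uninfected injured library 1 and 0.206 for Atp6v0d2 without infected uninjured library 2).

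Interferon-gamma response genes rose in 31 of 32 cases in infected uninjured against uninfected injured muscle (31 adjusted over the list alone), with a median of 3.78 (camera adjusted p = 8.79e-86, and adjusted p = 0.103 with an estimated correlation). MHC class I genes rose in 20 of 21 cases (20 adjusted over the list alone; 2.65e-24, and adjusted p = 0.109 with an estimated correlation) and MHC class II genes in 10 of 15 (12 adjusted over the list alone; 1.57e-07, and adjusted p = 0.233 with an estimated correlation). Glycolysis and hypoxia genes rose in 21 of 24 cases and fell in 1 (the same adjusted over the list alone; 4.98e-16, and adjusted p = 0.109 with an estimated correlation). Inflammatory monocyte genes rose in 12 of 20 and fell in 2 (12 and 3 adjusted over the list alone; 1.36e-07, and adjusted p = 0.103 with an estimated correlation). Cytokines and chemokines rose in 10 of 24 and fell in 3 (12 and 3 adjusted over the list alone; 8.45e-05, and adjusted p = 0.296 with an estimated correlation). Dissociation stress genes rose in 8 of 24 and fell in 1 (the same adjusted over the list alone), with a camera adjusted p of 0.0236, lost without uninfected injured library 2 (0.0856), and adjusted p = 0.637 with an estimated correlation.

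Lower in infected uninjured than in uninfected injured muscle were lipid handling and lysosome genes, 16 of 26 with 1 higher (19 and 2 adjusted over the list alone), at a median of −1.59 (camera adjusted p = 3.64e-18, and adjusted p = 0.103 with an estimated correlation). Cell cycle genes fell in 23 of 34 cases (24 adjusted over the list alone), with a median of −1.39 and Stmn1 at −2.07 ± 0.17 (camera adjusted p = 1.02e-11, and adjusted p = 0.302 with an estimated correlation). Muscle repair factors fell in 11 of 20 cases and rose in 3 (12 and 4 adjusted over the list alone), with Mmp12 at −4.25 ± 0.26 (camera adjusted p = 8.29e-05, and adjusted p = 0.103 with an estimated correlation). Lists that did not pass had adjusted p of 0.444 for type I interferon, 0.573 for alternative activation, 0.343 for resident macrophages, 0.0585 for complement and efferocytosis receptors, 0.364 for iron and haem handling and 0.333 for oxidative phosphorylation. Their higher and lower members were 3 and 5 of 25, 5 and 3 of 19, 7 and 5 of 23, 5 and 7 of 19, 7 and 3 of 19, and 2 and 1 of 37. Adjusted over the list alone they were 3 and 5, 5 and 4, 7 and 6, 5 and 7, 8 and 4, and 1 and 0. The median of resident macrophage genes was −0.17 while their mean was 0.85, and camera gave the upward direction.

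Between infected uninjured and uninfected injured muscle edgeR called 2623 genes, 1409 higher and 1214 lower, 1416 of them over 2-fold. The count was 1301 without infected uninjured library 2. Without scaling beyond the total count, the median of all genes moved to −0.14 and 40.7% of calls were higher, against 53.7% with TMM scaling.

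The share of UMIs from the interferon-gamma response list was then measured cell by cell in the retained cells. Its median was 0.115% and 0.112% in the uninfected injured libraries, 0.384% and 0.518% in the infected injured libraries, and 0.691% and 0.820% in the infected uninjured libraries. The range from the 10th to the 90th percentile of cells was 0.0528% to 0.223% in uninfected injured library 1, 0.142% to 0.886% in infected injured library 1 and 0.305% to 1.33% in infected uninjured library 1. With each cell thinned to 3449 UMIs the medians were 0.116% and 0.116%, 0.377% and 0.493%, and 0.696% and 0.812%.

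No difference in the variation between cells of a library could be established with 2 libraries per group. The median distance between cells was 0.405 and 0.412 in uninfected injured, 0.408 and 0.368 in infected uninjured and 0.400 and 0.395 in infected injured libraries. Infected injured libraries lay 0.0107 below uninfected injured ones on average (0.398 ± 0.00326 against 0.408 ± 0.00522, SD, n = 2), with an exact two-sided permutation p of 0.333, the smallest this design allows. Infected injured and infected uninjured libraries overlapped (exact permutation p = 1), as did infected uninjured and uninfected injured libraries (exact permutation p = 0.667). By the entropy of clusters, a different measure, the libraries did not overlap in any pair of groups, with means of 3.21 bits in uninfected injured, 1.41 bits in infected uninjured and 1.89 bits in infected injured libraries (exact permutation p = 0.333 for each pair). The clusters were drawn on all cells pooled, before equal numbers were taken. Uninfected injured libraries held 5907 and 1586 of the 11467 retained cells. That imbalance can shape the cluster borders, so the entropies do not settle an order of the groups.

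Cells in clusters led by markers of other cell types were also present after the CD64 and MerTK sort. Those in a cluster led by Nkg7, Gzma, Cd3g and Thy1, called T or NK cell-like, made up 3.89% and 2.88% of kept cells in infected uninjured libraries and 2.17% and 1.22% in infected injured libraries. Their exact 95% intervals were 2.42% to 5.88%, 2.18% to 3.72%, 1.35% to 3.30% and 0.526% to 2.38%. In uninfected injured library 1 the share was 0.382% (0.243% to 0.573%), and in library 2 it was 0 of 1601 cells, which allows a share of up to 0.187%. Neutrophil-like cells, in a cluster led by S100a9, Camp, Ngp and S100a8 in which monocyte genes such as Ly6c2 and Plac8 were also high, made up 1.43% and 0.937% in uninfected injured, 0.185% and 0.257% in infected uninjured and 2.07% and 0.760% in infected injured libraries. In infected injured library 1, with 20 cells in this cluster, Camp was at 0.0742 CPM and S100a9 at 4.01 CPM over all kept cells. Within the cluster they were at 3341 and 6415 CPM, and Fcgr1 was at 171% and Csf1r at 77.2% of the level of retained cells. The name follows the leading genes of the cluster and need not hold for most of its cells, so these are not shares of neutrophils. The neutrophil-like share also depended on the clustering. At Leiden resolution 0.5 it was 29.3% and 28.5% in uninfected injured against 1.14% and 1.82% in infected injured libraries. That cluster of 2250 cells was also led by Cd209a, Ifit3 and Mgl2, so it took in other cells. S100a8 was at 54.0 and 100 CPM over all kept cells of uninfected injured libraries, against 11337 CPM within the neutrophil-like cluster of all libraries at resolution 1. In infected uninjured library 2, with 5 neutrophil-like cells, the neutrophil markers stood at 1488 CPM over all kept cells and 226 CPM in retained cells. The level within the cluster need not be that of its uninfected injured cells, so these levels cannot decide a neutrophil share of that size. At resolution 1 the shares of the injured groups overlapped, so the order of these groups is not settled.

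On sums over all kept cells, 7 of 12 measured T cell markers rose and 2 fell in infected injured against uninfected injured muscle (camera adjusted p = 8.33e-10, and adjusted p = 0.303 with an estimated correlation). The T cell receptor chain gene Cd3g was at 7.79 and 4.98 CPM in infected injured, 34.5 and 16.6 CPM in infected uninjured and 0.511 and 0 CPM in uninfected injured libraries. NK cell markers rose in 2 of 6 cases, Klrk1 and Ccl5 (adjusted p = 0.00313, and adjusted p = 0.303 with an estimated correlation), although Ccl5 is also made by macrophages. Endothelial markers rose in 3 of 5 cases (Flt1, Pecam1 and Ly6c1), with an adjusted p of 5.74e-05 and adjusted p = 0.222 with an estimated correlation, and the most abundant, Fabp4, is also a macrophage gene. The adjusted p was 0.790 for macrophage or monocyte, 0.609 for dendritic cell, neutrophil and fibroblast, and 0.529 for muscle fibre markers in that comparison. In infected injured against infected uninjured muscle, 6 of 12 T cell markers fell and 1 rose (camera adjusted p = 5.90e-04, and 0.505 with an estimated correlation), and 3 of 12 dendritic cell markers fell, Naaa, Clec9a and Xcr1 (0.0069, and 0.354). Macrophage or monocyte markers rose in 8 of 27 cases and fell in 2 (2.54e-04, and 0.351), and endothelial markers rose in 2 of 5, Fabp4 and Kdr (0.0109, and 0.351). The adjusted p was 0.706 for neutrophil, 0.546 for NK cell and muscle fibre and 0.490 for fibroblast markers. In infected uninjured against uninfected injured muscle, 9 of 12 T cell markers rose and 2 fell (9.09e-10, and 0.457), 2 of 6 NK cell markers rose and 1 fell (0.0298, and 0.457), and 9 of 27 macrophage or monocyte markers fell and 5 rose (0.0101, and 0.457). The adjusted p was 0.269 for dendritic cell, fibroblast and muscle fibre, 0.292 for endothelial and 0.535 for neutrophil markers.

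B cell, mast cell, pericyte, erythroid and platelet lists had too few measured members for a test. Their most abundant markers reached 17.9 CPM for Cd79b, 8.88 CPM for Hdc, 4.02 CPM for Acta2, 5.32 CPM for Hbb-bs and 2.98 CPM for Clec1b, apart from the plasma cell gene Jchain at 66.2 CPM in infected injured library 2 and the platelet gene Ppbp at 6.60 CPM in uninfected injured library 2. S100a8 stood at 644 CPM and Camp at 210 CPM in infected uninjured library 2, against 38.4 and 0.217 CPM in infected uninjured library 1.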

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

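The tests of the T or NK cell-like cells in this part were chosen, or changed, after their results were seen. These cells lie outside the cells that the comparisons use, and stood out because their share was higher in every infected library than in the uninfected ones. The share was 3.89% in infected uninjured library 1, 2.88% in infected uninjured library 2, 2.17% in infected injured library 1 and 1.22% in infected injured library 2. In uninfected injured libraries it was 0.382% and 0 of 1601 cells (up to 0.187%).

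The gate asks for CD64 and MerTK, and the T or NK cell-like cells carried macrophage transcripts, with C1q genes at 59.9%, 80.3% and 67.0% of the level of retained cells in infected uninjured library 2 and infected injured libraries 1 and 2, and 61.9% in uninfected injured library 1, but at 8.80% in infected uninjured library 1. Free RNA in the droplets would give cells of any type a like amount, yet they held more C1q UMIs per cell than neutrophil-like cells in both libraries with at least 20 cells of each type. The ratio was 12.7 in infected injured library 1 (bootstrap 95% interval 5.84 to 35.6) and 2.11 in uninfected injured library 1 (1.13 to 3.53), which argues against free RNA as the whole cause in these libraries, though in the latter neutrophil-like cells reached 36.9% of the C1q level of retained cells, so a part from free RNA stays open there. Chance pairing of separate cells would be limited to the doublets expected from loading, 1.58%, 0.781% and 0.529% in the 3 infected libraries with high C1q. Yet 76.8%, 76.2% and 50% (4 of 8 cells) of the T or NK cell-like cells held over 10% of the C1q level of retained cells. The exact 95% intervals were 63.6% to 87.0%, 52.8% to 91.8% and 15.7% to 84.3%. Neutrophil-like cells averaged 8.53%, 12.1% and 4.48% of that level there, so some cells could pass the cutoff without a paired macrophage. These shares thus argue against chance pairing as the only source in these libraries. In uninfected injured library 1 that share was 60.9% (exact 95% interval 38.5% to 80.3%) against 5.07% expected, which did not reach the bound of 10 times the expected share, so chance pairing stays open there. A T or NK cell that stayed joined to a macrophage through the sort remains a candidate explanation: such cells had at least 46.4 more genes per cell than retained cells at the same number of UMIs, which met the prediction in its first form, but a control added after those values were seen showed 63.6 more genes in infected uninjured library 1, where C1q was low, so joined cells and T cells with more genes cannot be told apart. Infection, which the design names, stays open as an untested biological explanation of the higher share.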

How the results depend on the processing

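No test in this part was chosen after its result was seen, and no alternative was added. Of the named genes and lists that were called, only Cd2 changed direction, in the third comparison, from −1.91 to 0.0562 (not called) over all kept cells, which include the T or NK cell-like cells. With the experiment as a replicate block, the calls between infected injured and uninfected injured muscle rose to 1597 (912 higher, 685 lower) and the higher calls between the infected groups to 1108; the block ended the calls of 3, 3 and 0 named genes in the 3 comparisons, given beside them, and changed no other call of a named gene or of a list with camera. Without scaling beyond the total count, 391 genes were higher and 749 lower in the first comparison. Without a count filter, 17300 genes were tested and it gave 1544 calls, 692 of them lower. In the third comparison, 774 genes were lower with a stricter filter (6971 genes tested) and 792 with equal cells per library (fewer UMIs, 10006 genes tested). Leaving out each library in turn, with a lone library assumed to vary like the others, gave 561 to 893 calls in the first comparison (386 to 532 higher, 175 to 382 lower), 370 to 1709 in the second (181 to 800 higher, 189 to 944 lower) and 1301 to 2630 in the third (804 to 1434 higher, 497 to 1224 lower). It ended 22 of 67, 38 of 69 and 10 of 74 calls of named genes, and settings other than the block ended 10, 10 and 8. DESeq2 called 884, 1237 and 2043 genes and limma 1016, 1513 and 2715. Of the 16 lists, 9, 11 and 10 passed in camera (9 to 11, 10 to 12 and 9 to 11 without single libraries), 0, 0 and 0 with an estimated correlation, and 4, 2 and 8 with fry. Entropy of clusters replaced the distance between cells with differences of −1.32, 0.480 and −1.80 bits, a different measure that follows cluster borders, and without thinning the first difference was −0.0349. The second, 0.00968, changed sign to −0.0173 without thinning (libraries overlapping) and to −0.0138 over all detected genes (not overlapping), so its direction is open. Thinning moved the interferon-gamma list share of uninfected injured library 2 to 0.116%. At Leiden resolution 0.5 the neutrophil-like share was 29.3% and 28.5% in uninfected injured and 1.14% and 1.82% in infected injured libraries, in a cluster also led by Cd209a, Ifit3 and Mgl2. At resolution 2.0 it was 1.83% in uninfected injured library 1. The same rule there also set aside 287 dendritic cell-like cells. Of these, 248 and 35 were in uninfected injured, 1 and 1 in infected uninjured and 2 and 0 in infected injured libraries. Apart from the smaller number of libraries, genes or cells where these are named, the cause was not tested. Infected uninjured library 1, the shallowest at 4448159 UMIs in 518 retained cells, limits what could be detected for low genes.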

Other observations

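Of the tests in this part, the co-marker test of Retnla was set before its result was seen, and the other tests of Retnla and of the interferon-gamma response list were chosen after. The test of 1 fraction for every list member took the place of another form after the result of that form was seen, and its members were limited to those called between the other groups after its own result was seen.

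Transcripts of Ifng, looked up after its values were seen, came almost wholly from the T or NK cell-like cells. These 106 cells held 208 of the 216 Ifng UMIs (96.3%) among the 4111 kept cells of the infected libraries, while the uninfected libraries held 4 Ifng UMIs, 3 of them in T or NK cell-like cells. Single cells accounted for other unusual values. In infected injured library 2, 1 cell held 418 of 425 Jchain UMIs, and in infected uninjured library 2, 4 cells held 3048 of 3352 Camp UMIs, although 14.7% of cells there had at least 1 Camp UMI.

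The genes of the sort were called in some comparisons, but each of these calls ended without at least 1 library. In infected injured against infected uninjured libraries, Fcgr1 rose by 0.65 ± 0.16 (edgeR adjusted p = 0.0231), while Mertk changed by −0.65 ± 0.16 (adjusted p = 0.0216) and Ptprc by −0.51 ± 0.14 (adjusted p = 0.036). Fcgr1 was also higher in infected injured than in uninfected injured libraries, by 0.62 ± 0.16 (adjusted p = 0.0333). In infected uninjured against uninfected injured libraries, Mertk was higher by 0.56 ± 0.16 (adjusted p = 0.0218) and Ptprc by 0.43 ± 0.14 (adjusted p = 0.0462). Without single libraries the adjusted p reached 0.329 for Fcgr1, 0.162 for Mertk and 0.246 for Ptprc. Cd68, a lysosomal membrane protein on which the cells were not sorted, rose by 1.19 ± 0.17 in infected injured against infected uninjured libraries (adjusted p = 0.00142) and changed by −1.08 ± 0.17 in infected uninjured against uninfected injured libraries (adjusted p = 6.28e-04). In the last of these comparisons, single genes of iron handling moved although their list did not pass. The siderophore-binding protein Lcn2 rose by 6.07 ± 0.67 (adjusted p = 7.80e-04, and 0.0580 over all kept cells), and the iron exporter Slc40a1 changed by −4.68 ± 0.62 (adjusted p = 1.73e-04).

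Retnla was concentrated in few cells. Those with at least 20 Retnla UMIs were 0.846% and 1.51% of retained cells in uninfected injured, 2.70% and 1.80% in infected uninjured, and 0 of 927 and 0 of 645 in infected injured libraries (up to 0.324% and 0.465%). Lower depth is argued against by the 565 UMIs that the lowest level of the other libraries would give at the depth of the shallower infected injured library. A mixture of the other groups' cells is argued against by an upper 95% limit of 1.38 CPM against at least 89.2 CPM in each other library. These levels cannot test a wrong label, since a swap of labels between groups would leave the same libraries low. Loss of a small set of Retnla-high cells stays open. Cells with a high score of 5 co-expressed genes (Mgl2, Mt2, Cd2, Egr1 and Fn1) were 2.27% and 2.79% in infected injured libraries against 16.2% and 23.6% in uninfected injured and 7.34% and 5.15% in infected uninjured libraries. The upper limit of 4.37% in infected injured library 2 passes the lower limit of 4.19% in infected uninjured library 2. The score also did not single out Retnla-high cells, since far more uninfected injured cells passed it than the 0.846% and 1.51% with at least 20 Retnla UMIs. Of these genes Mgl2 and Cd2 were themselves called lower against both groups and Fn1 against uninfected injured only. Against infected uninjured libraries, the calls of Mgl2 (adjusted p = 0.0544) and Cd2 (0.0780) ended without infected uninjured library 2, and that of Cd2 also without infected injured library 1 (0.136) and with equal cells per library (0.157). At Leiden resolution 1, a cluster led by Cd209a and Retnla held 391 and 105 uninfected injured, 4 and 0 infected uninjured, and 0 and 0 infected injured cells. At resolution 2.0, a cluster led by Retnla and Mgl2 held 426 and 146, 4 and 0, and 0 and 0 cells in that order. Another, led by Retnla and C4b, held 0 and 0, 148 and 517, and 21 and 26. Clusters are drawn from expression, so a loss of cells and a lower expression of these genes cannot be told apart here. The combination of infection and injury remains an untested biological explanation.

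The interferon-gamma response list in infected injured cells lay between its levels in the other groups. A mixture in 1 proportion of cells in the fixed states of those groups was tested by the cells between the edges of those states. Such a mixture would give a share of these cells within the range of the other groups. In experiment 1 the share was 5.10% in infected injured cells (95% interval 3.77% to 6.73%), against 1.92% and 2.65%. In experiment 2 it was 23.9%, against 7.88% and 7.08%. The edges in experiment 1 lay close together, at 0.232% and 0.290% of UMIs. The interval covers counting error only, and each experiment held 1 library per group. Both shares exceeded that range, but variation between pools was not measured, so these shares alone do not decide it. Such a mixture would also place every gene at 1 fraction of the way between the other groups. A single fraction of the way for every list member is argued against by the fractions of the 31 members called between the other groups, which spread over 0.424 and 0.389 in the 2 experiments (10th to 90th percentile) and ranked alike in both. Their Spearman correlation was 0.766 (bootstrap 95% interval 0.5 to 0.913 with members taken as independent), 0.738 with TMM scaling, and 0.660 over all 33 members with a fraction. Among the 12 most abundant of the 31 it was 0.517 (Spearman test p = 0.0849), so the agreement was not established for those alone. The fractions of the 31 members as a set thus also argue against the mixture in 1 proportion, as the level of Retnla did. After thinning, the higher infected injured median of 0.493% still lay between the other groups. Thinning keeps the expected share of a list, so these medians could not test whether depth was the cause. Infected injured cells were also spread over clusters. At Leiden resolution 1, a cluster led by Dnase1l3 and Iigp1 held 542 of 927 and 382 of 645 infected injured retained cells. It held 46 and 60 infected uninjured and 5 and 0 uninfected injured cells. Clusters led by Upp1, by Ccl5 and by Csf1 held 82 and 68, 18 and 66, and 201 and 65 infected injured cells. An intermediate response in individual infected injured cells remains a hypothesis, found and tested on the same data. Mixtures of more than 2 states were not tested.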
